A study of Mus musculus with 21 samples.

How the data were processed

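The data are 21 single-cell RNA sequencing libraries of mouse olfactory epithelium, prepared with 10x Genomics 3' chemistry from papain-dissociated tissue sorted for live nucleated cells (Draq5 positive, DAPI negative). The labels give 7 Fzd1cKO, 6 Control and 8 CD1 libraries with ages, 4 batches and, for 3 libraries, odor stimulation. Per the labels the authors made the deposited counts with Cell Ranger on the mm10 genome; its version and the annotation release are not given in the sources used here. The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization, and a lowest total of 500 UMIs per barcode. The other deposited files hold gene IDs with symbols and cell barcodes, which are no measurement. The labels do not say what the letters NE in some titles mean, nor why titles of CD1 libraries say OSNs in batch MOLNG-2407 and OE in MOLNG-2453.

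Gene IDs in both feature lists in use (55406) were analysed, and 55227 of these had the same ID in the reference annotation, from which coordinates were taken. Genes in only one feature list were left out of the comparisons and took at most 0.104% of the UMIs of a library. Barcodes with at least 500 genes and at most 15% mitochondrially encoded UMIs were kept (92610 of 98414), and 4157 doublets called with Scrublet were removed. Scrublet's automatic threshold failed in most libraries, so the expected doublet share of each library, with the highest scores, was removed. Kept cells per library were 3015 to 10050 in the Fzd1cKO and Control libraries and 1217 to 3854 in CD1, before doublets were removed.

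Cells were clustered with scanpy 1.11.5 in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9) on 2000 variable genes, 30 principal components and 15 neighbours, with Leiden clustering at resolution 1 (leidenalg 0.10.2, python-igraph 0.11.9). Omp, immediate early and heat shock genes were left out of the variable genes. Clusters were named from marker genes written before the data were examined. The margin between mature and immature scores was raised from 0.5 to 1 after clusters and class sizes had been seen and before any gene was tested, and 0.5 was kept as an alternative. Clusters of the neuronal lineage are called intermediate when these scores lay within the margin, or when more of their leading genes belonged to another class than to their own. The margin applied to 21.8% to 32.8% of cells in the 13 Fzd1cKO and Control libraries and up to 3.58% in CD1. Leading genes of another class applied to up to 10.5% and up to 35.7% (P0), so that intermediate clusters made up 31.6% of cells at P0 and 9.38% at P21 in CD1. Clusters with few UMIs and no clear markers, and those of other lineages led by genes of another class, were left without a name.

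UMIs were summed per library and class where a class had at least 20 cells. Counts were scaled by TMM and tested with edgeR 4.0.16 (filterByExpr, robust quasi-likelihood fits, two-sided tests, Benjamini-Hochberg adjustment at 0.05) in R 4.3.3. Genotype was tested over 6 pairs of libraries of the same age, batch and stimulation, with the pair as block. Stimulation was tested in 13 libraries with genotype and each combination of age and batch in the model. Age in CD1 was a slope on age rank with batch in 7 libraries, and postnatal day a slope with batch, genotype and stimulation. Interactions of genotype with day and of stimulation with genotype were tested in the same way. Lists of genes written before the data were examined were tested with camera of limma 3.58.1 at a correlation of 0.01 on log2 CPM, again with an estimated correlation, and with fry.

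A mature cell was assigned the odorant receptor with at least 3 UMIs and the highest count, and receptors with at least 30 cells were compared with edgeR on cells per library. Robust estimation failed for that small table, so plain estimation was used there. Shares of classes were compared by exact sign flips over pairs, with 0.5 cells added in log odds, and along age by permutation over all orders. Fzd1 levels have 95% exact Poisson intervals, which cover counting error alone. For detection at equal depth, 2000 UMIs were drawn per cell.

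Fzd1 and Omp are named in every comparison. Otherwise the text names up to 10 genes higher and 10 lower by size of change among those past the test, with a mean log2 CPM of at least 4 and the same direction in every pair, leaving out clone names. It also names up to 4 members past the test and up to 2 others per list, up to 5 receptors higher and 5 lower, and, with fewer than 5 genes past the test, these and the 5 with the smallest p. This rule, the tests and the first set of alternatives were fixed before the data were examined. Those alternatives were DESeq2 1.42.0, its size factors in edgeR (RLE), no low-count filter, at least 1000 genes per cell, doublets kept, Leiden resolution 2, other sets of libraries or blocks, other denominators, receptor minimums of 2 and 5 UMIs, and leave-one-out. Alternatives without P3 libraries, without receptor genes, without the 2 pairs most unlike in sex-linked genes and with the margin of 0.5 were chosen after seeing the data.

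The edgeR comparisons were tested on simulated data with the libraries' own dispersions and planted changes. At changes of 2 times, 36.1% were recovered in the genotype design, 11.2% in the stimulation design and 2.07% in the CD1 design, with false shares of 22.3%, 19.3% and 73.3% of all calls, mostly receptors. In the CD1 design the planted change was spread over the whole range of ages. With dispersions set to the trend, the false shares were 3.37%, 4.5% and 5.71%. Sustentacular-like cells were left out of the genotype comparison because 1 pair reached 20 cells in both libraries. A result that the naming rule would include along postnatal day is not reported here, for a reason that does not depend on its value.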

Results

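Single-cell RNA sequencing was done on dissociated mouse olfactory epithelium, the sheet of the nose in which olfactory sensory neurons (OSNs) arise from basal progenitors throughout life. Fzd1 encodes Frizzled1, a Wnt receptor, and the question set by the study's design is what its conditional deletion, described there as one in mature OSNs, does to the epithelium around a critical period in the first postnatal week. The libraries at P10 and some of CD1 lie after that week. The 21 libraries fell into 7 Fzd1cKO (conditional knockout) libraries, 6 Control libraries and 8 libraries of wild-type mice of the outbred CD1 strain. The Fzd1cKO and Control libraries came at P5, P7 and P10 (batch MOLNG-3334) and at P3 and P7 (batch MOLNG-3650), with 1 library per genotype and age in a batch. In batch MOLNG-3650, 3 further libraries were labelled as odor stimulated, at P3 for both genotypes and at P7 for Fzd1cKO. The CD1 libraries covered E13.5, E18.5, P14 and adult (batch MOLNG-2453) and P0, P3, P7 and P21 (batch MOLNG-2407), 1 library per age. The labels do not say whether libraries came from separate or pooled animals, so each p measures only the spread between these libraries.

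After low-quality barcodes and doublets were removed, 88453 of 98414 barcodes remained. Total UMIs per library ran from 51108683 (Control P10) to 109905225 (Control P3) in the Fzd1cKO and Control libraries and from 7015427 (P21) to 24920333 (E18.5) in CD1. Median UMIs per kept cell were 10265 to 19409 and 1347 to 8240 in these sets. Clusters were named from fixed marker genes, so the classes are called mature OSN-like, immature OSN-like and progenitor-like (globose basal and immediate neuronal precursor cells). Each of the 13 Fzd1cKO and Control libraries held 246 to 1332 mature OSN-like cells, and the CD1 libraries held 178 to 1932, apart from E13.5 with 3.

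Where Fzd1 was measured came first. Fzd1 (ENSMUSG00000044674, mm10 chromosome 5, 4753839 to 4758035) was highest outside the neuronal lineage. Summed over all libraries, it reached 40.6 CPM (UMIs per total UMIs, scaled; 95% exact Poisson interval 38.1 to 43.2) in fibroblast-like cells, 19.7 (15.8 to 24.3) in horizontal basal-like stem cells and 17.2 (14.1 to 20.9) in sustentacular-like support cells. These sums join sets with unlike means: fibroblast-like cells averaged 59.9 CPM in CD1, 26.0 in Control and 25.2 in Fzd1cKO libraries, and progenitor-like cells 4.34, 2.05 and 1.63. Along the neuronal lineage it was 1.87 CPM (1.73 to 2.01) in progenitor-like cells and 0.797 (0.678 to 0.932) in 15959 mature OSN-like cells, a total of 157 UMIs. Macrophage-like cells, assumed without a test to lack the transcript, gave 0.585 (0.159 to 1.5), an interval that covers the value of mature OSN-like cells. This was the highest of the blood-derived classes. T or NK-like cells gave 0.288 (0.0073 to 1.6) and neutrophil-like cells 0 (0 to 1.29), intervals that cover it too. B cell-like, erythroid-like and mast or basophil-like cells had 0 UMIs of Fzd1 at lower total counts. These classes cannot settle how much of the OSN value is background. In CD1 mature OSN-like cells, Fzd1 was 0.253 to 1.46 CPM from 1 to 3 UMIs per library, with rho = -0.64 and r = -0.44 across 7 ages (permutation p = 0.139 and 0.331; adjusted p = 0.694; r = -0.37 without the ages farthest from the middle). With 2000 UMIs drawn per cell, rho was -0.11. These batches are too small (3 and 4 libraries) for a value within each.

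Whether the deletion could be read in the transcript was asked next. In mature OSN-like cells Fzd1 was 0.729 ± 0.223 CPM (SD, n = 7) in Fzd1cKO and 0.826 ± 0.306 (SD, n = 6) in Control libraries. It was lower in 4 of 6 pairs of libraries of the same age, batch and stimulation, with a log2 difference of -0.15 (SE 0.20, adjusted p = 0.757). Differences were 0.13 in immature OSN-like cells (adjusted p = 0.965) and -0.29 in progenitor-like cells (adjusted p = 0.501). Each library gave 2 to 20 UMIs of Fzd1 in mature OSN-like cells. An SE of 0.20 leaves little room for a loss of 2 times in the UMIs counted, but how many of these came from the cells themselves was not measured, and which part of the gene was deleted is not given in the sources used here.

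**Figure D1:**
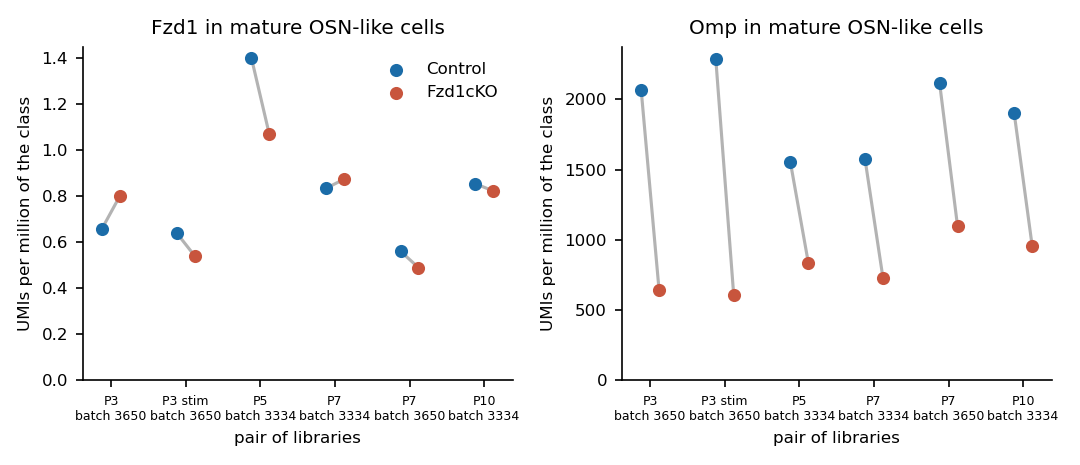
Fzd1 and Omp in mature OSN-like cells of the Fzd1cKO and Control libraries, in CPM, with 1 point per library and lines joining the 6 pairs. Omp was lower in Fzd1cKO in each pair (608.5 to 1098 against 1553 to 2290 CPM), while Fzd1 lay between 0.489 and 1.40 CPM in both genotypes.

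The main comparison asked which transcripts of mature OSNs differ between the genotypes. Omp (ENSMUSG00000074006, chromosome 7, 98143359 to 98145502), which encodes olfactory marker protein, an abundant protein of mature OSNs, was 812 ± 190.2 CPM in Fzd1cKO and 1917 ± 301 CPM in Control libraries (SD, n = 6). Omp was lower in 6 of 6 pairs, with a log2 difference of -1.32 (SE 0.22, adjusted p = 0.458). By pair, the difference was -0.89 at P5, -1.14 at P7 and -0.96 at P10 in batch MOLNG-3334, -0.95 at P7 in batch MOLNG-3650, and -1.90 and -2.10 at P3 without and with odor stimulation. Over the alternative settings its adjusted p ran from 4.06e-07 (DESeq2) to 0.464. Without the 2 P3 pairs it was 5.32e-05, and the log2 difference was -0.99 (SE 0.06). Among the pairs left there, P5 and P7 of batch MOLNG-3334 were unlike in sex-linked genes. Omp lies inside the gene Capn5 on the same strand, so reads of the longer gene cannot be excluded at this position.

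Among Wnt receptors, Ror1 (ENSMUSG00000035305), a receptor tyrosine kinase of the non-canonical Wnt pathway, was 0.943 ± 0.467 CPM in Fzd1cKO and 0.275 ± 0.165 in Control (n = 6; log2 1.64, SE 0.34). Fzd5 (ENSMUSG00000045005), another Frizzled receptor, was 0.723 ± 0.155 and 0.307 ± 0.120 CPM (log2 1.15, SE 0.27). Both were higher in 6 of 6 pairs, at levels near that of Fzd1 itself. Adjusted p was 0.458 over all genes and 0.0287 each when adjusted over the list alone. Without the 2 P3 pairs 0 genes of that list passed adjusted over the list alone. The mature OSN-like cells of all 13 libraries gave 98 UMIs of Ror1 and 95 of Fzd5. In progenitor-like cells Ror1 stood at 43.7 CPM and Fzd5 at 0.419, and carry-over from other cells was not measured. Among adhesion and guidance genes, Chl1 (a neural adhesion molecule) was 2.51 ± 0.673 against 1.25 ± 0.424 CPM (log2 0.96, SE 0.25, 6 of 6 pairs), and Sema3c (a secreted semaphorin) had a log2 difference of 1.04 (SE 0.38, 5 of 6). The zonal gene Rdh10, a retinol dehydrogenase, was 8.79 ± 4.10 against 4.66 ± 0.819 CPM (log2 0.72, 6 of 6), and the protocadherin Pcdh10 had 0.33 (5 of 6), all at adjusted p = 0.458. The membrane protein Stoml3 was 2341 ± 782 against 2862 ± 374 CPM (log2 -0.42, lower in 5 of 6; -1.07 and -1.28 in the P3 pairs and -0.20 to 0.10 in the others), and the exchanger gene Slc24a4 had a log2 difference of 0.31.

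Of the gene lists, 4 shifted lower and 1 higher as sets. The 81 ribosomal protein genes fell (median log2 -0.34, 79 of 81 below 0, adjusted p = 3.66e-15), as did 27 nuclear-encoded oxidative phosphorylation genes (median -0.39, 27 of 27 below 0, adjusted p = 3.19e-07), 20 unfolded-protein and stress response genes (-0.21, 20 of 20, adjusted p = 2.14e-05) and 12 heat shock genes (-0.28, 12 of 12, adjusted p = 0.00123). The 27 axon guidance genes rose (median 0.29, 24 of 27 above 0, adjusted p = 0.00148). Each of these 5 calls was lost with an estimated correlation (adjusted p = 0.498 with an estimated correlation for each), and with fry (adjusted p = 0.400 each). No member passed on its own, either over all genes or adjusted over the list alone. Examples are Uqcrb of respiratory complex III (log2 -0.48, SE 0.26), the electron carrier Cycs (-0.49, SE 0.27), Rpl5 (-0.35, SE 0.15), Rps4l (-0.64), the stress regulator Atf4 (-0.29), the endoplasmic reticulum protein Creld2 (-0.31), and the chaperones Hspd1 (-0.20) and Hspa1b (-0.50).

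These shifts moved with the P3 libraries. In the P3 pairs the log2 difference per gene rose with gene span across 8145 genes (rho 0.73 without and 0.72 with stimulation; genes are not independent replicates), against -0.22 to 0.11 in the other 4 pairs. With genes parted by span into 3 sets, the shortest had a median of -0.81 and the longest of 0.46 in the unstimulated P3 pair. Mature OSN-like cells of the P3 Fzd1cKO libraries lay 97.2% and 98.3% in 1 cluster that held 6.08% and 8.69% of those of P3 Control. Ribosomal protein genes took 2.09% and 2.07% of their UMIs, against 3.82% and 3.38% in P3 Control, and the activity-linked calcium-binding gene S100a5, chosen after its values were seen, took 1721 and 1559 CPM against 6518 and 5907. The other Control libraries had 2191 to 3133 CPM of S100a5 and Fzd1cKO P7 of batch MOLNG-3334 had 1749, so for this gene P3 Control stood high. Without the 2 P3 pairs, an alternative chosen after seeing the data, 0 lists passed with camera (smallest adjusted p = 0.408). There the medians were -0.03 for ribosomal proteins, 0.01 for oxidative phosphorylation, -0.03 for the stress response, -0.01 for heat shock and 0.05 for axon guidance.

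**Figure D2:**
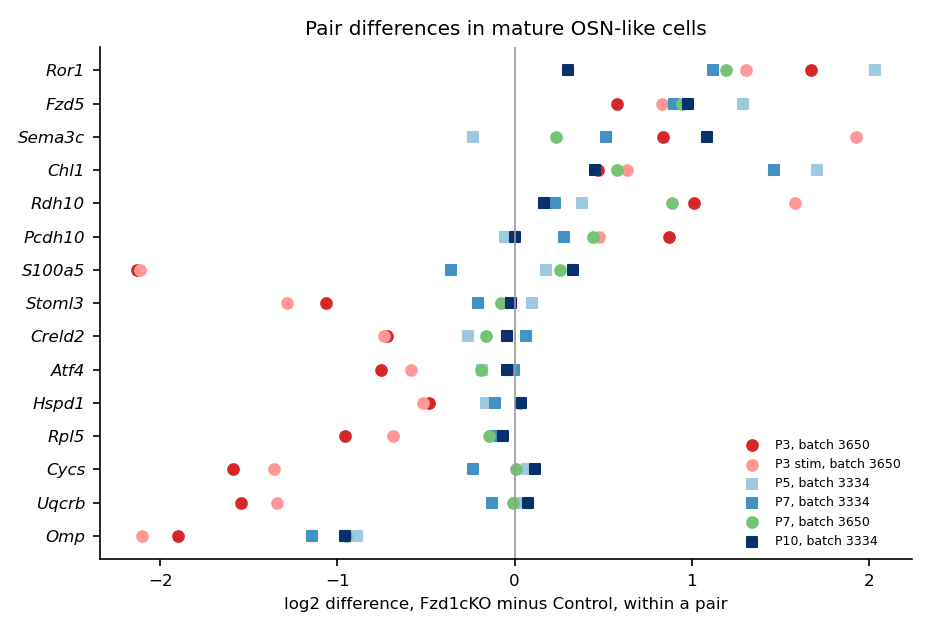
Log2 differences of Fzd1cKO minus Control in mature OSN-like cells for 15 genes, with 1 point per pair and the P3 pairs marked. Omp lay below 0 in each of the 6 pairs (-0.89 to -2.10), and Uqcrb had -1.54 and -1.34 in the P3 pairs and -0.13 to 0.07 in the others.

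The remaining lists did not pass. Adjusted p was 0.0990 for Wnt receptors and planar polarity (median 0.14, 12 of 19 above 0) and for glomerular sorting molecules (median 0.21, 11 of 14), and 0.124 for intracellular Wnt genes. It was 0.400 for olfactory transduction, 0.707 for the immature OSN programme, 0.250 for proliferation, 0.523 for immediate early genes, 0.197 for activity-state genes and 0.187 for presynaptic release. Receptor choice regulators gave 0.418, zonal genes 0.929, axon injury and apoptosis 0.225, mitochondrially encoded genes 0.359 and cilia 0.225. Odorant receptors gave 0.225 (1 gene higher over all genes; 8 higher and 13 lower adjusted over the list alone), trace amine-associated receptors 0.248 and sex-linked genes 0.359. The sex-linked list cannot weigh a sex difference, since its members went opposite ways and the test asks for 1 direction. In the P5 and P7 pairs of batch MOLNG-3334, log2 differences were 11.8 and 8.96 for Xist. For Ddx3y they were -6.99 and -7.25. Markers of sustentacular cells (0.225), blood (0.742) and stroma (0.742) did not pass either. For the immature programme (median -0.01, mean 0.02) and for stroma (median 0.03, tested as lower) the signs of median, mean and test differed.

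With edgeR, 1 of 18736 genes passed in this comparison and 1153 had an unadjusted p under 0.05. The gene was the odorant receptor Olfr1500 (ENSMUSG00000054526, chromosome 19, 13826882 to 13830488; 4.52 ± 6.94 against 0.0300 ± 0.0477 CPM, n = 6, log2 6.70, SE 0.35, adjusted p = 0.0422), higher in 4 of 6 pairs and carried by P10 (368 UMIs) and P3 (144 UMIs). The receptors next in rank were Olfr453 and Olfr92 (log2 -7.25 and -7.80, adjusted p = 0.05004 each), Olfr270 (-7.68, adjusted p = 0.0789) and Olfr135 (7.77, adjusted p = 0.120). DESeq2 called 14 genes, 10 of them receptors and without Olfr1500. Olfr1500 was also not called at Leiden resolution 2, with all 13 libraries, with doublets kept, or without P7 or P10 of batch MOLNG-3334 or either P3 pair. Leaving out the P3 pair gave 6 genes and leaving out the stimulated P3 pair 0. Leaving out both gave 61 genes, 56 of them receptors, and 4 with receptors left out of the test. The pairs left after both were dropped include P5 and P7 of batch MOLNG-3334, which were unlike in sex-linked genes. Differences of receptors that have almost no UMIs in one genotype depend on the prior count of the fit, and in simulated data of this design 42 receptors and 3 other genes were called falsely among 202 calls.

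Cells earlier in the lineage were asked the same question. In immature OSN-like cells the oligopeptide transporter gene Slc15a2 (ENSMUSG00000022899) was 10.0 ± 4.80 CPM in Fzd1cKO and 2.62 ± 1.32 in Control (n = 6; log2 1.91, SE 0.31, adjusted p = 0.316), higher in 6 of 6 pairs. Omp was 12.1 ± 5.45 against 29.3 ± 11.5 CPM (log2 -1.19, SE 0.24, adjusted p = 0.433). The lipoxygenase gene Alox5 had a log2 difference of 3.73 (6 of 6 pairs), the receptors Olfr130 and Olfr743 had 7.12 and -6.22, and the transcript A330044P14Rik had -4.75 (adjusted p = 0.316 each). By edgeR 0 of 15392 genes passed, with 1503 at an unadjusted p under 0.05, and DESeq2 called 0. Leaving out P7 of batch MOLNG-3650 gave 2 genes, and leaving out P5 or P7 of batch MOLNG-3334 gave 1 each. The count was 61 without the low-count filter and 44 at Leiden resolution 2. It was 20 in batch MOLNG-3334 alone and 52 in batch MOLNG-3650 alone. Without the P3 pairs, where gene span again moved with the difference (rho 0.66 and 0.64), 23 genes passed, among them Slc15a2 (log2 1.52, adjusted p = 0.0485) and Omp (-0.85, adjusted p = 0.0406), out of ranges of 1.5e-04 to 0.628 and 0.00567 to 0.628 over the alternatives.

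In progenitor-like cells, Kctd14 (ENSMUSG00000051727) was 1.99 ± 0.615 CPM in Fzd1cKO and 3.87 ± 1.34 in Control (n = 6; log2 -1.04, SE 0.18, adjusted p = 0.430), lower in 6 of 6 pairs. The receptor Olfr1168 had a log2 difference of 3.78 (6 of 6 pairs) and Omp one of -0.57 (SE 0.20), both at adjusted p = 0.430. With edgeR 0 of 21356 genes passed, with 2019 at an unadjusted p under 0.05; DESeq2 called 8. Without the P3 pairs (span rho 0.73 and 0.69) 11 genes passed, 11 of them receptors. Sustentacular-like cells reached 20 cells in both libraries of 1 pair alone, so that no comparison could be made there.

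Whether the genotype difference changes over P3 to P10 was tested as an interaction with postnatal day in mature OSN-like cells. The genes that passed were 13 of 18736 (5 higher and 8 lower per day), all odorant receptors, while 5922 had an unadjusted p under 0.05. Olfr635 had a slope of 2.83 log2 per day (adjusted p = 0.00209) and Olfr97 of 2.56 (0.00219), while Olfr642 had -7.38 (0.0157) and Olfr181 -7.74 (0.0214). Omp had 0.15 per day (adjusted p = 0.129) and Fzd1 0.03 (adjusted p = 0.827). The count rested on single pairs: it was 4608 without P5, 39 without P7 and 3743 without P10 of batch MOLNG-3334, and 104 without P3, 85 without stimulated P3 and 7 without P7 of batch MOLNG-3650. DESeq2 called 2763 genes, 77 of them receptors, and with the P3 pairs left out 171 passed, 165 of them receptors. Receptors were 133 of the 4608 genes without P5 and 124 of the 3743 without P10. Without the P3 pairs 550 of 18047 genes had an unadjusted p under 0.05, so the breadth of the shift depended on those pairs.

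Odor stimulation was compared in 3 stimulated libraries against unstimulated libraries of the same age, batch and genotype; the odor and its duration are not given in the sources used here. Immediate early genes, which neuronal activity induces within minutes, did not pass as a list (22 genes, median log2 0.04, 14 above 0, adjusted p = 0.422). Fos had a log2 difference of 0.50 (SE 0.31, higher in 2 of 3) and the nuclear receptor gene Nr4a1 of 0.48 (SE 0.28, 3 of 3), both at adjusted p = 1. Fos stood at 4.40 to 12.3 CPM in the libraries of batch MOLNG-3650, stimulated or not, and at 208 to 742 CPM in those of batch MOLNG-3334. Activity-state genes had a median of 0.05 (11 of 16 above 0, adjusted p = 0.379). Trace amine-associated receptors, which detect volatile amines, rose as a list (median 2.18, 8 of 11 above 0, adjusted p = 0.0308), a call lost with an estimated correlation (adjusted p = 0.569 with an estimated correlation) and with fry (0.980). Examples are Taar7d with a log2 difference of 4.79 (7 and 3 UMIs in the stimulated P3 libraries, 0 in the unstimulated P3 libraries, 41 and 19 in the P10 libraries) and Taar5 with 3.86 (15 UMIs in stimulated P7). Markers of blood (median -1.82, adjusted p = 0.0137) and stroma (median -0.48, adjusted p = 0.00219) fell as lists in the stimulated libraries, calls lost with an estimated correlation (adjusted p = 0.569 and 0.575 with an estimated correlation) and with fry (0.980 each). No member of these 3 lists passed on its own, over all genes or adjusted over the list alone; haemoglobin Hbb-bs had -1.86 and decorin Dcn -1.84, at adjusted p = 1 each. The other lists had adjusted p of 0.355 or more. Median and mean, or median and test, differed in sign for 6 of these: Wnt receptors, the immature programme, heat shock, mitochondrially encoded genes, sex-linked genes and sustentacular markers.

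With edgeR 0 of 18644 genes passed for stimulation in mature OSN-like cells, with 251 at an unadjusted p under 0.05. DESeq2 called 37, and 4 passed without stimulated Fzd1cKO P3. In the 7 libraries of batch MOLNG-3650 alone 167 passed, 154 of them receptors. The smallest p belonged to receptors, among them Olfr92 (log2 8.45), Olfr1276 (-8.90) and Olfr16 (14.43), at adjusted p = 0.170 each; adjusted over the list alone, 5 receptors were higher and 3 lower. Omp had a log2 difference of 0.06 and Fzd1 of -0.23, both at adjusted p = 1. In immature OSN-like cells 6 of 15961 genes passed (5 higher and 1 lower), all receptors: Olfr1427 had 9.78 (adjusted p = 0.0282; 149 UMIs in stimulated Control P3 and 127 in stimulated Fzd1cKO P7) and Olfr313 -6.43 (adjusted p = 0.0137, lower in 3 of 3). This count was 31 without stimulated Fzd1cKO P3 and 1 without stimulated Control P3 or stimulated Fzd1cKO P7. In the 7 libraries of batch MOLNG-3650 alone it was 194, with 182 receptors. Whether stimulation acted differently by genotype could rest on P3 alone in Control. There edgeR gave 0 of 19833 genes (575 at an unadjusted p under 0.05), DESeq2 62 and the fit without stimulated Fzd1cKO P7 1, with Olfr665 nearest (log2 13.64, adjusted p = 0.126).

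The receptor repertoire was compared by the receptor that each mature OSN-like cell carried. A receptor could be assigned to 90.8% to 98.5% of mature OSN-like cells in the 13 libraries. Olfr6 was carried by 9 cells in Fzd1cKO and 27 in Control libraries (log2 -1.69, lower in 5 of 6 pairs), and Olfr524 by 30 and 14 cells (log2 1.14, higher in 6 of 6), both at adjusted p = 0.486. Of 34 receptors with 30 or more cells, 0 passed with edgeR and 0 with DESeq2, and 2 and 1 had an unadjusted p under 0.05.

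Cell composition was compared between the genotypes as shares of all kept cells. Mature OSN-like cells made up 16.1% ± 9.31 in Fzd1cKO and 17.5% ± 9.02 in Control libraries (SD, n = 6), lower in 6 of 6 pairs, with a log2 odds difference of -0.17 ± 0.110. The exact two-sided sign-flip p was 0.0313, the smallest that 6 pairs allow, and the adjusted p over 11 classes was 0.344. The direction turned with a class margin of 0.5, chosen after seeing the data (23.7% against 18.6%, log2 odds 0.39, higher in 2 of 6 pairs), 2 of 6 pairs were higher with at least 1000 genes per cell, and 3 of 6 at Leiden resolution 2 (log2 odds -0.09, exact p = 0.313). Olfactory ensheathing glia-like cells, which wrap OSN axons, made up 0.343% ± 0.0639 against 0.229% ± 0.143 and were higher in 5 of 6 pairs (log2 odds 0.89, exact p = 0.0625, adjusted p = 0.344). Their log2 odds difference was 0.53 without the stimulated P3 pair and, in an alternative chosen after seeing the data, 0.22 without both P3 pairs (0.370% against 0.316%). Immature OSN-like cells made up 4.79% ± 3.32 and 6.41% ± 2.35 (log2 odds -0.63, exact p = 0.438, n = 6), and progenitor-like cells 26.2% ± 9.53 and 25.8% ± 9.36 (log2 odds 0.03, exact p = 0.500, n = 6). Both directions turned without the P3 pairs, to log2 odds of 0.08 for immature OSN-like cells (6.18% against 5.76%, higher in 3 of 4 pairs) and -0.03 for progenitor-like cells. The immature difference was -0.37 without the stimulated P3 pair and -0.32 without the unstimulated P3 pair.

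The CD1 libraries asked how the mature OSN-like class differs from late gestation to adulthood. Its cells lay in different clusters by age: 79.8% in cluster 10 at E18.5, 75.0% in cluster 1 at P14 and 69.9% in cluster 0 in the adult, while those of batch MOLNG-2407 lay in clusters 1, 2 and 5. Slopes therefore do not separate change within cells from change in which cells make up the class. Cnga4, Cnga2, Pde1c, Omp, Gap43 and Gng8, named below, were also markers that named the mature or immature class. Most such markers are members of the transduction list or the immature programme, so these slopes are not independent of how cells were classed. Of 21 transduction genes 11 rose, though the call for the list was lost with an estimated correlation (adjusted p = 0.575 with an estimated correlation). Cnga4 (ENSMUSG00000030897), a subunit of the cyclic-nucleotide-gated channel that opens on odor binding, had a slope of 0.38 log2 per step of age (SE 0.04, adjusted p = 0.00115). Its level went from 106 CPM at E18.5 to 515 in the adult in batch MOLNG-2453, and from 232 at P0 to 599 at P21 in batch MOLNG-2407. The partner subunits Cngb1 (0.28, adjusted p = 0.00320) and Cnga2 (0.26, adjusted p = 0.00864) and the phosphodiesterase Pde1c (0.25, adjusted p = 0.0108) rose with it, as did Omp (0.25, SE 0.05, adjusted p = 0.0108). Of 21 genes of the immature programme 13 fell, and here too the call for the list was lost (adjusted p = 0.575 with an estimated correlation). The growth cone protein Gap43 (ENSMUSG00000047261) had a slope of -0.46 (SE 0.05, adjusted p = 0.00139), from 1947 to 202 CPM in batch MOLNG-2453 and from 376 to 189 in batch MOLNG-2407. The G protein subunit Gng8 (-0.51, adjusted p = 0.00135), the actin regulator Marcksl1 (-0.48, adjusted p = 0.00107) and the tubulin Tubb2b (-0.39, adjusted p = 0.00107) fell too.

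**Figure D3:**
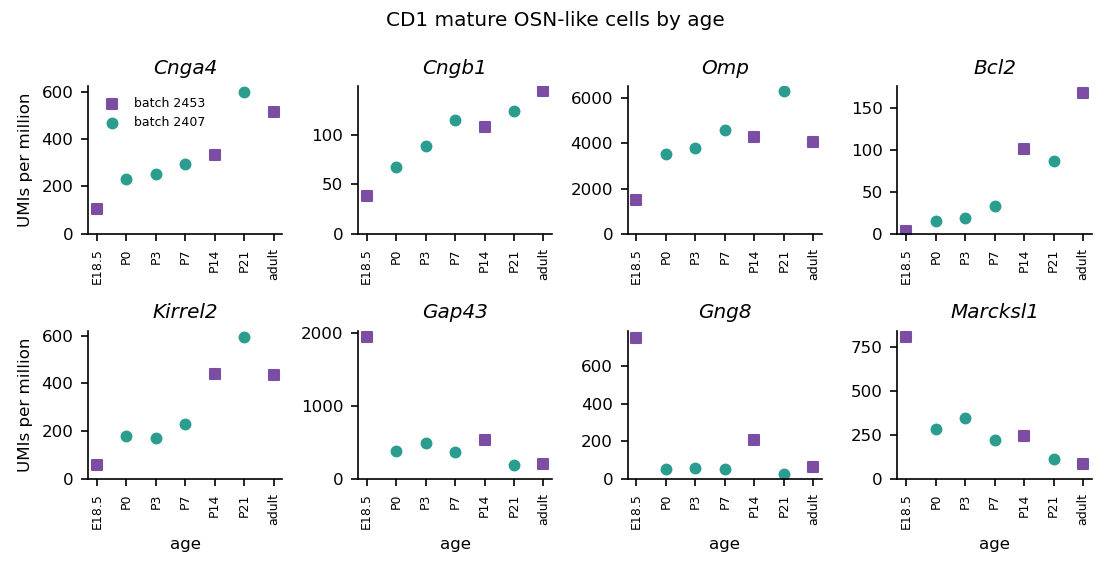
Levels of 8 genes in CD1 mature OSN-like cells by age, in CPM on a linear axis, with 1 library per age and the batches in separate colours. Cnga4, Cngb1, Omp, Bcl2 and Kirrel2 lay higher at the oldest than at the youngest age of each batch, and Gap43, Gng8 and Marcksl1 lower.

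Steep slopes, smaller than those of some receptors, included that of the survival factor Bcl2 (ENSMUSG00000057329; 0.76 per step, SE 0.08, adjusted p = 0.00180), which went from 3.56 to 168 CPM in batch MOLNG-2453 and from 15.2 to 87.1 in batch MOLNG-2407. The synaptic scaffold gene Dlg2 (0.72, SE 0.06, adjusted p = 0.00105) also rose steeply. Of 14 glomerular sorting genes 4 rose: Kirrel2 at 0.50 (adjusted p = 0.00973), Epha5 at 0.49 (0.0104), Epha7 at 0.47 (0.00315) and Sema7a at 0.40 (0.0161). For this list the call was lost with an estimated correlation (adjusted p = 0.784 with an estimated correlation), and 11 of 14 slopes were above 0. Others that rose were Cd27 and the potassium channel Kcnn2 (0.49 each), the peptide gene Pth2 (0.66), Pcp4l1 (0.57), Lrrc3b (0.45), the immediate early gene Ier2 (0.34), the nuclear envelope protein Lbr (0.31), the transcription factor Nfix (0.23) and the calcium sensor Syt1 (0.20). Among genes that fell were Gng3 (-0.67), Ly6h (-0.59), the growth cone protein Basp1 (-0.59), the intermediate filaments Prph (-0.56) and Vim (-0.51), Ldha (-0.54), the vesicle protein Rab3c (-0.48) and the calcium buffer Calb2 (-0.22).

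With camera 8 lists passed along age, and each call was lost with an estimated correlation (adjusted p = 0.575 with an estimated correlation for transduction, the immature programme and receptors, 0.697 to 0.851 for the others). By list, 11 of 21 transduction genes rose (13 adjusted over the list alone; adjusted p = 2.60e-06 for the list) and 13 of 21 immature programme genes fell (17 adjusted over the list alone; adjusted p = 6.48e-10). Odorant receptors rose as a set (median 0.33, 395 of 559 above 0, adjusted p = 1.69e-05), with 41 higher and 6 lower over all genes and 40 and 6 adjusted over the list alone; Olfr175 had 3.84 (adjusted p = 0.00119) and Olfr1140 -1.31. Sorting molecules (median 0.09, adjusted p = 0.0233, 4 rose, 5 adjusted over the list alone) and mitochondrially encoded genes (median 0.14, adjusted p = 0.00683, 2 rose, 7 adjusted over the list alone, mt-Nd2 at 0.17) were higher. Oxidative phosphorylation (median -0.12, adjusted p = 7.79e-07, 7 fell, 16 adjusted over the list alone, Cox7c at -0.20), ribosomal proteins (median -0.09, adjusted p = 1.82e-08, 7 fell, 14 adjusted over the list alone, Rps28 at -0.24) and stroma markers (median -0.38, adjusted p = 0.0248, 0 fell) were lower. With fry, adjusted p was 0.0247 for transduction, 0.0259 for the immature programme and 0.0832 for sorting molecules and oxidative phosphorylation; activity-state genes passed with fry alone (adjusted p = 0.0247, against 0.224 with camera). The other lists had adjusted p of 0.224 or more, and median, mean and test differed in sign for both Wnt lists, the stress response, axon injury and sustentacular markers.

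In all, 1241 of 11546 genes passed along age in 7 libraries (631 higher and 610 lower), with batch in the model. Median UMIs per mature OSN-like cell were 8713 at E18.5, 2643 at P14 and 1149 in the adult in batch MOLNG-2453 and 3300 to 4426 in batch MOLNG-2407. The count was 43 without E18.5, 421 without the adult, 796 without P3 and 636 with a minimum of 1000 genes per cell. Without E18.5, 31 of the 37 genes named for age no longer passed, Omp among them (log2 0.18, adjusted p = 0.246, with 0.21 and 0.116 without a batch term). In simulated data of this design, 2.07% of changes of 2 times were found and 73.3% of 30 calls were false (21 receptors and 1 other gene). Those changes were spread from the youngest to the oldest age, so they were shallower per step than most slopes named here. Receptors made up 51 of the real 1241 genes, so the simulated false share cannot be carried over to them.

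The course over P3 to P10 was also followed in mature OSN-like cells of the 13 Fzd1cKO and Control libraries. Among genes that fell with day, Cntnap2 (ENSMUSG00000039419), a neurexin-like adhesion molecule, had -0.49 log2 per day (SE 0.05, adjusted p = 0.00799), from 72.1 and 89.0 CPM at P5 to 8.39 and 14 at P10 in batch MOLNG-3334 and from 114 to 204 at P3 to 31.8 to 58.6 at P7 in batch MOLNG-3650. The channel regulator Fgf14 (ENSMUSG00000025551; -0.52, SE 0.06, adjusted p = 0.0129), the presynaptic Erc2 (-0.27, adjusted p = 0.0319), the cadherin Cdh18 (-0.26, adjusted p = 0.0341) and the basement membrane collagen Col4a2 (-0.22, adjusted p = 0.0276) fell too. The ciliary kinesin Kif19a rose (0.30 per day, SE 0.03, adjusted p = 0.00799), as did the activity-induced genes Btg2 (0.26), Jun (0.20) and Gem (0.21), Bcl2 (0.22, adjusted p = 0.0292) and the actin-binding Tmsb10 (0.22). Omp had 0.09 (adjusted p = 0.220) and Fzd1 -0.08 (adjusted p = 0.418).

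Of 17785 genes, 202 passed along postnatal day (69 higher and 133 lower, 1 receptor); batch MOLNG-3334 held P5, P7 and P10 and batch MOLNG-3650 P3 and P7. P3 is the youngest age, and its Fzd1cKO libraries stood higher in genes of long span (rho 0.73 and 0.72); a relation of the slopes with span was not tested. The count was 725 without Control P3, 344 without stimulated Control P3, 58 and 28 without Fzd1cKO and Control P5, 15 and 26 without Fzd1cKO and Control P10, and 57 without Fzd1cKO P7 of batch MOLNG-3334. In batch MOLNG-3650 it was 12 and 42 without Fzd1cKO and Control P7, 16 without stimulated Fzd1cKO P7 and 19 without Fzd1cKO P3. DESeq2 called 1532 genes. Without the 4 P3 libraries 1062 passed, 150 of the 202 among them, and in Control libraries alone 161 passed, 134 of them receptors and 11 shared.

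Composition in CD1 was followed over the 8 ages. Mature OSN-like cells rose from 0.249% of cells at E13.5 and 5.01% at E18.5 to 47.0% at P14 and 76.9% in the adult in batch MOLNG-2453, and from 14.9% at P0 to 61.9% at P21 in batch MOLNG-2407. Their share followed age with rho = 0.976 and r = 0.957 (permutation p = 4.00e-04 and 1.00e-04, adjusted p = 0.00476 and 0.00119 over 12 classes), and r was 0.942 without E13.5 and the adult. Fibroblast-like cells fell from 61.0% to 0.159% and from 2.20% to 0.2% in these batches (rho = -0.929, r = -0.715, permutation p = 0.00223 and 0.00253, adjusted p = 0.0134 and 0.0152; r = -0.770 without E13.5 and the adult). B cell-like cells rose from 0.332% to 2.11% and from 0.335% to 0.998% (rho = 0.881, r = 0.828, permutation p = 0.00724 and 0.00456, adjusted p = 0.0290 and 0.0183; r = 0.817 without those ages). Of 12 classes these 3 passed by rho; 1 did without E13.5, E18.5, P21 or the adult. Shares were also taken of mature, immature and progenitor-like cells alone, without intermediate clusters. Mature OSN-like cells then had rho = 0.976 (adjusted p = 0.00119) and progenitor-like cells -0.929 (adjusted p = 0.00335), against -0.238 among all kept cells. Immature OSN-like cells had -0.738 (adjusted p = 0.0458 by rho and 0.0508 by r). Intermediate clusters were added in an alternative not fixed beforehand. Mature OSN-like cells then had rho = 1.0 (adjusted p = 0.0002) and progenitor-like cells -0.976 (adjusted p = 0.00079). For immature OSN-like cells rho stayed at -0.738 (adjusted p = 0.0611 by rho and 0.0442 by r). The batches hold 4 ages each, so no correlation within one is given. Titles of batch MOLNG-2407 name OSNs and those of MOLNG-2453 OE, and a difference in sort or dissected area between them would change shares joined across batches.

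**Figure D4:**
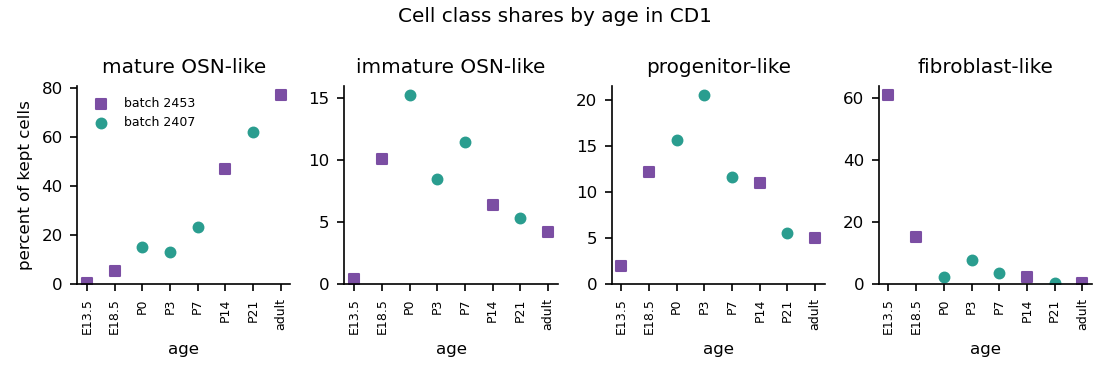
Shares of all kept cells in the 8 CD1 libraries by age, in percent, for mature OSN-like, immature OSN-like, progenitor-like and fibroblast-like cells, with 1 library per age. Mature OSN-like cells made up 76.9% in the adult and 61.9% at P21, and fibroblast-like cells 61.0% at E13.5.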

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

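Values in 39 sets of libraries were searched for a library standing apart, by the gap to its nearest neighbour over the range of its group, and 2 were found; chance alone gives about 1 in 20. Fzd1 in mature OSN-like cells of Control libraries was 1.40 CPM at P5 against 0.561 to 0.855 in the other 5, a gap of 0.651 of the range, above the limit for 6 libraries. The percent of mature OSN-like cells assigned a receptor was 90.8 in Control P3 against 95.4 to 97.6 in the other 5, a gap of 0.683 of the range. The genotype difference changed with postnatal day in 13 genes by the interaction test, all odorant receptors. In that test 5922 of 18736 genes had an unadjusted p under 0.05.

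Outside the genes analysed, 3 genes present in only one of the feature lists stood above the Control libraries in both Fzd1cKO P3 libraries. In unstimulated and stimulated P3, AL663045.1 was 1.57 and 1.22 CPM (Control 0.309 to 0.71), AC119183.1 was 1.77 and 1.65 CPM (Control 0.408 to 0.645) and CT010467.2 was 136.9 and 133 CPM (Control 10.3 to 35.7). Fzd1cKO P5 was also above for AL663045.1 (0.89) and CT010467.2 (39.9), and unstimulated Fzd1cKO P7 of batch MOLNG-3650 for AC119183.1 (0.772). These genes were chosen after their values were seen.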

How the results depend on the processing

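Alternatives without P3 libraries, without receptor genes, without the 2 pairs most unlike in sex-linked genes and with a class margin of 0.5 were chosen after seeing the data. Why counts moved was not tested except where stated, and counts do not say which genes passed. The count of genes for genotype in mature OSN-like cells was 1; it was 14 with DESeq2, 21 without the low-count filter, 0 with doublets kept (1159 at an unadjusted p under 0.05), 3 at Leiden resolution 2 and 0 with the margin of 0.5. It was 0 with receptor genes left out (1052 at an unadjusted p under 0.05), 3 with all 13 libraries, 69 in batch MOLNG-3334 alone and 0 in batch MOLNG-3650 alone (3227). It was 0 without the pair block (1521), 0 without the stimulated pair (372), 0 without the 2 pairs most unlike in sex-linked genes (1346), 61 without the 2 P3 pairs and 4 when receptors were also left out. Leave-one-out gave 0 to 6. The 2 pairs most unlike in sex-linked genes belong to batch MOLNG-3334 and stay in when the P3 pairs are left out.

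In immature OSN-like cells (0 genes) the count was 61 without the low-count filter, 44 at Leiden resolution 2, 20 in batch MOLNG-3334 alone, 52 in batch MOLNG-3650 alone, 4 without the 2 pairs most unlike in sex-linked genes and 23 without the P3 pairs, and leave-one-out gave 0 to 2. In progenitor-like cells (0 genes) it was 8 with DESeq2, 1 at Leiden resolution 2, 14 in batch MOLNG-3334 alone and 11 without the P3 pairs, and leave-one-out gave 0. For genotype by day (13 genes) it was 2763 with DESeq2, 89 without the filter, 3 at Leiden resolution 2, 1 with the margin of 0.5, 0 without receptor genes (5780 at an unadjusted p under 0.05), 37 with all 13 libraries and 171 without the P3 pairs, and leave-one-out gave 7 to 4608.

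For stimulation in mature OSN-like cells (0 genes) the count was 37 with DESeq2, 7 without the filter and 167 in the 7 libraries of batch MOLNG-3650, and leave-one-out gave 0 to 4. In immature OSN-like cells (6 genes) it was 15 with DESeq2, 10 with RLE, 42 without the filter, 0 with the margin of 0.5 (491 at an unadjusted p under 0.05), 0 without receptor genes (148) and 194 in the 7 libraries, and leave-one-out gave 1 to 31. For stimulation by genotype (0 genes) it was 62 with DESeq2, 15 without the filter and 297 in the 7 libraries, and leave-one-out gave 0 to 1.

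Along age in CD1 (1241 genes) the count was 636 with at least 1000 genes per cell and 43 in postnatal libraries only, and leave-one-out gave 43 to 1269. Along postnatal day (202 genes) it was 1532 with DESeq2 and 1062 without the 4 P3 libraries, and leave-one-out gave 12 to 725. Of the CD1 classes whose share followed age (3), 1 passed by rho with at least 1000 genes per cell, where mature OSN-like cells were not tested and fibroblast-like and B cell-like cells both passed by r (adjusted p = 0.0172 each), and leave-one-out gave 1 to 3. Lists past the test by genotype (5) were 0 with an estimated correlation, 0 with fry and 0 without the P3 pairs; by stimulation (3) they were 0 and 0, and along age (8) 0 with an estimated correlation and 3 with fry, of which activity-state genes had not passed with camera. Fzd1 by genotype, receptor choice and shares by genotype kept their side of the test in each alternative, though directions turned. For shares this says little, since the exact p was at its smallest 0.0625 with 5 pairs and 0.125 with 4. With 6 pairs the smallest, 0.0313 for the mature share, gave an adjusted p of 0.344 over 11 classes. For receptor choice, 2 receptors were left to test without the P3 pairs. The mature share went from lower to higher with the margin of 0.5 (log2 odds 0.39). Without the P3 pairs the immature share went from -0.63 to 0.08 and the progenitor share from 0.03 to -0.03. The progenitor share was also -0.02 at Leiden resolution 2, and fibroblast, intermediate and neutrophil shares turned in some alternatives.

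Among named genes, Slc24a4 by genotype changed sign with the margin of 0.5 (-0.078) and in batch MOLNG-3334 alone (-0.023). Omp changed sign for genotype by day without the P3 pairs (-0.0085), and for stimulation in the 7 libraries (-0.0073) and in leave-one-out (-0.22 without stimulated Control P3 to 0.23 without stimulated Fzd1cKO P3). Of 624 values for 37 genes along age in CD1, 102 no longer passed, and of 299 for 13 genes along day 73 no longer passed. By genotype in mature OSN-like cells 9 of 459 values no longer passed and 17 newly passed.

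The comparison in sustentacular-like cells, stimulation in immature OSN-like cells at Leiden resolution 2, and stimulation by genotype without stimulated Control P3 could not be fitted.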

Other observations

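Levels of other Wnt receptors set Fzd1 in context. In mature OSN-like cells of the 13 Fzd1cKO and Control libraries, the Frizzled receptor Fzd3 was 115 ± 22 CPM (SD), the Wnt receptor Ryk 90.7 ± 6.44, the Wnt co-receptor Lrp6 46.8 ± 7.72 and the planar polarity cadherin Celsr2 39.0 ± 4.40, against 0.773 for Fzd1, 1.43 for Fzd7, 1.05 for Fzd6 and 0.171 for Fzd2. In progenitor-like cells Fzd3 was 181 ± 32.7 and Ryk 142 ± 7.82 CPM, and Ror1 (43.7), the polarity gene Vangl2 (41.7) and Fzd2 (31.7) stood far above their levels in mature OSN-like cells (0.697, 2.38 and 0.171). Immature OSN-like cells lay between, with Vangl2 at 21.7 and Fzd2 at 7.24 CPM.

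Of the tests below, those of unspliced or nuclear RNA, of a deletion restricted to mature cells and of Omp were chosen after the result was seen. Mature OSN-like cells of the P3 Fzd1cKO libraries stood apart from P3 Control by cluster and by gene span. Longer genes were higher there in mature OSN-like cells (rho 0.717 or more in both P3 pairs), so more unspliced RNA in those libraries is a candidate explanation. The nuclear transcript Malat1, chosen after its values were seen, was lower there (28231 against 32683 and 25102 against 32041 CPM). It was also lower in the P7 pair of batch MOLNG-3334 (28574 against 31782 CPM), where rho with gene span was 0.11. The transcript CT010467.1, chosen in the same way, was higher at P3 (3424 against 2454 and 3151 against 2158 CPM). These genes cannot decide on the share of nuclear RNA as a whole. The tables argue against an effect of a deletion restricted to mature cells, since progenitor-like cells showed the same relation (rho 0.690 or more), and against an effect of the genotype at every age, since the P3 differences had r = 0.0288 with the mean of the other 4 pairs. A difference in handling between these libraries stays open, as does a genotype effect at P3 that reaches progenitors.

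Omp was lower in each Fzd1cKO library than in its paired Control. Its mean log2 difference in the 4 pairs other than P3 was -0.98, close to the loss of 1 of 2 copies, so a deletion driver inserted at Omp may account for it; the labels used here do not name the driver. The transduction list had a median log2 difference of -0.01 (-0.00518) in those pairs. Its members include most of the markers that named the mature class, so this value cannot weigh a general loss of mature transcripts. Within 1 Mb of Omp, 7 of 23 genes had a p under 0.05 without the P3 pairs, against at most 4 in 1000 random draws, so sequence that came with such a driver could also play a part. An effect of Fzd1 on Omp stays open, as untested.

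The genotype calls were weighed against other splits of the labels within pairs. In mature OSN-like cells 17 of 32 splits gave as many genes as the real 1 (highest other 7), so chance could not be excluded there; at an unadjusted p under 0.05, 8 of 32 gave as many as the real 1153 (highest other 1461). With 0 real genes, 32 of 32 splits give as many by construction in immature OSN-like cells (highest other 9), progenitor-like cells (0) and receptor choice (0), which says nothing about chance. At an unadjusted p under 0.05, the real 1503 genes in immature OSN-like cells were the most of the 32 splits (highest other 1498), while 7 of 32 reached the real 2019 in progenitor-like cells and 4 of 32 the real 2 in receptor choice. In immature OSN-like cells, splits that set the 2 P3 pairs against each other gave 134 to 189 genes. The real count there was 537 without the stimulated and 517 without the unstimulated P3 pair, so this rank follows the P3 pairs. For stimulation the 4 splits are too few for a share under 0.05, with 0 genes real and 1 the highest other in mature OSN-like cells (4 splits as large), and 6 and 11 in immature OSN-like cells (2 splits as large).

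Without the 2 pairs most unlike in sex-linked genes (P5 and P7 of the batch with P10) 0 genes passed, as at the median of 0 over the other ways to leave out 2 pairs. A count this near its floor cannot weigh a sex difference. In these 2 pairs Fzd1cKO was higher in Xist (log2 11.8 and 8.96) and lower in Ddx3y (-6.99 and -7.25). The called gene, Olfr1500, differed by 0 and 0.79 in those pairs, with 2 UMIs or fewer per library, and by 6.03 at P10 and 5.60 at P3. Its mean over the 4 pairs other than P3 was 1.71 and rested on P10. The stimulated P3 pair also differed in sex-linked genes, by less (Ddx3y -1.83, Xist 1.23, chosen after their values were seen). The gene also differed at P10, a pair other than P3 and alike in sex-linked genes. With 1 gene and 1 such pair, a sex difference or the P3 libraries as the source of this call could not be weighed.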
